A study of Homo sapiens with 16 samples.

How the data were processed

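Cytoplasmic RNA and RNA from polysomal sucrose fractions were sequenced from 2 human small cell lung cancer lines, H69 and H69M, each carrying a lentiviral shRNA against EIF6 (sheIF6) or a control shRNA (shNTC). Line, shRNA and fraction make 8 groups with 2 libraries each, 16 in all. The labels number the libraries of a group but do not say that they are separate cultures, so p-values measure only the spread between these samples. The deposited table holds the authors' raw counts per gene for 56832 gene names. The submitters' processing notes name STAR and HTSeq and the human genome GRCh38, without versions and without the strand setting. Genes that overlap on opposite strands, and families with near-identical members or pseudogenes such as ribosomal protein genes, can therefore share reads. Gene positions were taken from GENCODE v29 by gene name, and 29502 of the names matched 1 gene.

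Library totals ran from 36005326 to 87269772 counts. Replicates differed by 24.8 to 244 times the variance expected from counting alone (chi-square per degree of freedom), with correlations of log CPM of 0.951 to 0.982. Depth was therefore not what limited the larger genes; the spread between 2 libraries was. Lower bounds against groups with no count use 3 counts over the group and cover counting error only.

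Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10, which left 23100, and scaled by TMM. One quasi-likelihood fit with robust dispersion held a mean for each of the 8 groups, with 8 residual degrees of freedom; the common dispersion was 0.153 and the median prior degrees of freedom 4.76. Contrasts were sheIF6 against shNTC in each line and fraction, the change of polysomal minus the change of cytoplasmic RNA (called polysome association), the difference of the knockdown between lines, H69M against H69 in shNTC libraries, and polysomal against cytoplasmic RNA in shNTC libraries. P-values were adjusted by Benjamini and Hochberg over all genes tested, and 0.05 was the limit. Levels are CPM, mean ± SD of 2 libraries; SE is the log2 change divided by the square root of F. Log2 changes are as edgeR fits them, and log2 CPM per library used a prior count of 2.

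The genes named for each knockdown contrast and for the line difference are EIF6, up to 6 adjusted-significant genes in each direction with the largest change, a mean raw count of at least 100 in the higher group and no overlap between the groups' libraries, leaving out clone, antisense, pseudogene and family names. For the difference between lines the limit was 5 in each direction. A fixed panel (with INSM1, NEUROD1, CHGA, REST, YAP1, HES1, VIM, CDH1, CDH2, ITGB4, MYC, MYCL, AXL, CD44, ATF4, CDKN1A and SBDS) and members of gene lists were added. Some genes of the panel and of the lists are not reported here. Sets of 40 gene lists were tested by camera in limma 3.58.1 with a preset correlation of 0.01, and also with an estimated correlation and by fry. Members of a list are given as past the limit over all genes, or adjusted over the list alone. These choices, and the alternatives listed next, were made before the data were examined.

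The alternatives were RLE scaling, scaling by total library size alone, no low-count filter, a stricter filter (at least 50 counts in at least 2 libraries), DESeq2 1.42.0, limma-voom, a fit of 1 line alone, the replicate number as a block, the block by numbered pair of libraries for polysome association, a fold threshold of 1 on the log2 scale, leaving out 46 mitochondrial and ribosomal RNA genes, and leaving out each of the 16 libraries in turn. When 1 library was left out, the lone library of its group was assumed to vary like the other groups. After the data had been seen, 8 more were added: the block within each line, 1 line alone with the block, leaving out genes over 5 times higher in the other line, leaving out the H69M polysomal libraries numbered 2, leaving out both libraries of 1 number of H69M shNTC, of H69M sheIF6 or of H69 shNTC, and a line difference taken from the sheIF6 libraries.

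Pairing of the libraries was checked from their deviations from the group mean. Within a line, libraries with the same number deviated together in all 6 pairs of groups (r = 0.168 to 0.280 in H69 and 0.172 to 0.578 in H69M); between the lines the 16 correlations ran from -0.107 to 0.0457. The labels do not state pairing, so values with the replicate block within each line (common dispersion 0.0881, 6 residual degrees of freedom) stand beside those without it where the block changes a call or moves a count of calls by over 1.5 times.

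The fit was tested on simulated data of 22256 genes with 50 genes changed at each fold and group sizes as here. In H69M cytoplasmic RNA it called 0 of 50 at 1.5-fold, 3 at 2-fold, 37 at 4-fold and 45 at 8-fold; in H69 cytoplasmic RNA 0, 2, 39 and 46; in polysomal RNA 0, 5, 35 and 43 (H69) and 0, 2, 32 and 46 (H69M). At most 3 unchanged genes were called per contrast. No change in polysome association was planted, so how well such changes are called was not measured. Camera called a planted list of 30 genes at 1.5-fold in cytoplasmic RNA of both lines and did not call an unchanged list there. Simulated genes and libraries were drawn independently. The simulation therefore cannot show how camera with the preset correlation acts on genes or libraries that deviate together. In H69M polysome association, where the 30 genes of the planted list were unchanged because both fractions carried it, camera called them at an unadjusted 0.05 (0.0486), so a list can pass there without a change. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.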

Results

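EIF6 mRNA was lower in both knockdown libraries than in both control libraries of the same line and fraction, in all 4 settings (n = 2 libraries per group). EIF6 encodes a factor that binds the large ribosomal subunit and keeps it from joining the small one; the gene lies on chromosome 20 (35278911 to 35284985, minus strand). In H69 it stood at 66.4 ± 1.91 CPM against 114 ± 2.82 in cytoplasmic RNA and at 227 ± 10.3 against 406 ± 24.4 in polysomal RNA, or 58.1% and 55.9% of control. In H69M it stood at 129 ± 46.0 against 184 ± 27.4 and at 111 ± 35.3 against 263 ± 85.5, or 69.9% and 42.4% of control. The 2 H69M cytoplasmic knockdown libraries, replicates 1 and 2, were at 161 and 96.3 CPM, the controls at 204 and 165. In edgeR the log2 changes were -0.78 (SE 0.295) and -0.84 (SE 0.295) in H69, and -0.52 (SE 0.294) and -1.24 (SE 0.298) in H69M. The H69M cytoplasmic value was -0.93 without H69M sheIF6 cytoplasmic replicate 1 and -0.18 without replicate 2. None passed after adjustment over all genes (adjusted p = 1, 0.956, 0.547 and 0.204; with the replicate block within each line 0.792, 0.572, 0.367 and 0.0884). The H69M polysomal change passed by DESeq2 (-1.22, adjusted p = 0.0149), and the H69 polysomal change in a blocked fit of H69 alone (-0.83, adjusted p = 0.0300). SBDS, whose product helps to release eIF6 from the ribosomal subunit, did not pass in either line (log2 -0.11 and -0.06 in H69, -0.25 and -0.36 in H69M).

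**Figure D1:**
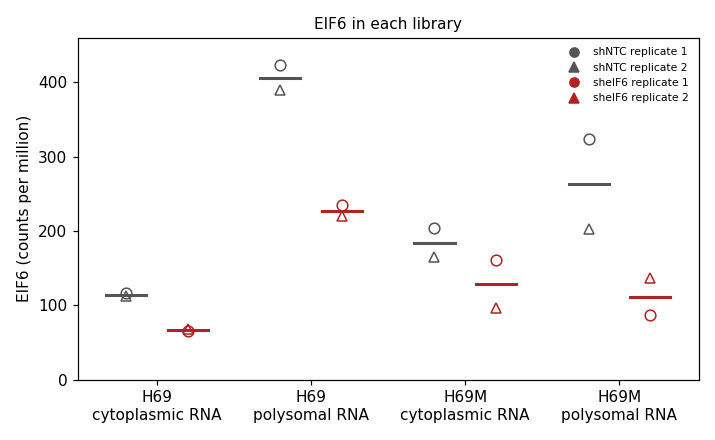
EIF6 level (CPM) in each library, by line and fraction, for shNTC and sheIF6. Bars are means of 2 libraries.

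H69M against H69, in control cells, asks how the 2 lines differ before knockdown. In cytoplasmic RNA of H69M, KRT17, a basal keratin, reached 958 ± 44.2 CPM with no count in H69 (at least 32339-fold higher, n = 2 per group). YAP1, the effector of the Hippo pathway, stood at 259 ± 20.2 against 0.234 ± 0.331 CPM (log2 10.08, adjusted p = 1.64e-05). The intermediate filament gene VIM stood at 2351 ± 630.5 against 9.01 ± 12.6 (8.03, adjusted p = 0.00689) and the receptor kinase AXL at 210 ± 78.7 against 0.439 ± 0.621 (8.88). The H69 control counts of YAP1 and AXL all lay in H69 shNTC cytoplasmic replicate 1, and nearly all of those of VIM. Without it the fitted values of the 3 genes were 16.6, 16.3 and 14.2, of which the first 2 stand against 0 and are no measure of size. The granule protein gene CHGA stood at 1.91 ± 1.74 against 146 ± 34.5 (-6.26, SE 1.50, adjusted p = 0.00938), a call lost without H69M shNTC cytoplasmic replicate 1 (-5.54, adjusted p = 0.0976). The neuroendocrine transcription factor gene INSM1 stood at 14.8 ± 19.3 against 1090 ± 330 (-6.20, adjusted p = 0.0361). Its 2 H69M controls, replicates 1 and 2, were at 1.15 and 28.4 CPM, and genes of H69 alone, chosen to be low in replicate 1, stood at 0.157 and 2.04% of their H69 level there. The INSM1 value was -9.89 (adjusted p = 0.0479) without H69M shNTC cytoplasmic replicate 2. The call was lost without H69M shNTC cytoplasmic replicate 1 (-5.26, adjusted p = 0.177) and without any 1 of the 8 H69 libraries, such as H69 shNTC cytoplasmic replicate 1 or 2 (-5.85 and -6.48, adjusted p = 0.118 and 0.0909). REST, the repressor of neuronal genes, stood at 40.1 ± 6.17 against 0.0390 ± 0.0552 CPM.

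Other genes with no count in H69 cytoplasmic RNA were F2RL2 (at least 5371-fold higher in H69M), COL5A3 (3331), ALPK2 (2841), MYH3 (2696) and PRRX1 (2277). Genes with no count in H69M were GABRA4 (24.9 ± 18.2 CPM in H69, at least 647-fold lower), GRIP2 (535), ST6GAL1 (476), HRASLS (417), IGKC (301) and GALNT14 (219). The GALNT14 call was lost without H69M shNTC cytoplasmic replicate 1 or 2 (adjusted p = 0.0604 and 0.0534). In the panel HES1 (log2 3.47), ITGB4 (3.53), CDH2 (4.36) and MYC (2.29) were also higher in H69M and CDKN1A lower (-0.64, adjusted p = 0.0469; blocked 0.0930). The CDKN1A call was lost without any 1 of the 8 H69 and 4 H69M shNTC libraries, such as H69 shNTC cytoplasmic replicate 1 or 2 (-0.58 and -0.70) and H69M shNTC cytoplasmic replicate 1 or 2 (-0.83 and -0.47). CD44 (1.41, adjusted p = 0.0608; blocked 0.00393) and NEUROD1 (-4.78, adjusted p = 0.0868; blocked 2.57e-05) passed with the replicate block within each line and not without it, and CDH1 (-0.15) and SBDS (0.41) did not pass. CD44 also passed without any 1 of the 4 H69 polysomal libraries (1.41 each) and NEUROD1 without H69M shNTC polysomal replicate 1 or 2 (-4.76 and -4.78); NEUROD1 was at -11.5 without H69M shNTC cytoplasmic replicate 2.

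Whole groups of genes separated the lines. Of 31 integrin and focal adhesion genes 27 were higher and 1 lower in H69M (camera adjusted p = 6.84e-20; adjusted p = 0.00590 with an estimated correlation). The same held for 23 of 25 genes of the non-neuroendocrine state, 18 of 22 YAP and TEAD targets, 19 of 25 matrix genes, 14 of 15 antigen presentation genes and 16 of 22 NF-kB genes (adjusted p = 0.0115, 0.00670, 0.0115, 0.00678 and 0.0353 with an estimated correlation). Of 32 neuroendocrine genes 22 were lower, among them SCG3 (log2 -7.34) and GRP (-6.43), and 1 was higher, BEX1 (1.42, 159 ± 45.05 against 59.1 ± 12.8 CPM). The SCG3 call was lost without H69 or H69M shNTC cytoplasmic replicate 1 (-7.08 and -6.41, adjusted p = 0.0569 and 0.113). The list's call was lost at adjusted p = 0.197 with an estimated correlation. Epithelial genes split: CDH3 (7.46), KRT18 (2.29) and KRT8 (1.82) were higher, and ESRP1 (-5.87), DSP (-4.33) and CLDN3 (-3.71) lower; the ESRP1 call was lost without H69M shNTC cytoplasmic replicate 1 (-5.52, adjusted p = 0.0551). In all 3738 genes were higher and 3249 lower in cytoplasmic RNA and 4251 and 3608 in polysomal RNA (with the block within each line 4306 and 3964, and 4812 and 4350); without H69 shNTC cytoplasmic replicate 1 the cytoplasmic count was 4530.

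Polysomal against cytoplasmic RNA, in control cells, asks which RNAs are enriched on polysomes. Mitochondrially encoded mRNAs, which are translated on mitochondrial ribosomes, were the most depleted class (median log2 -2.64 in H69, 11 of 13 genes past the limit, and -1.93 in H69M, 4 of 13; n = 2 per group). Their share of all counts fell from 5.13 ± 0.280% to 0.626 ± 0.341% in H69 and from 3.63 ± 0.949% to 0.820 ± 0.693% in H69M. Nuclear-retained long noncoding RNAs were depleted too (-1.94, 6 of 10 genes, and -1.25, 2 of 10). With an estimated correlation neither list passed (adjusted p = 0.415 and 0.402 for mitochondrially encoded mRNAs, 0.30 and 0.239 for nuclear-retained RNAs, H69 and H69M). With the block within each line 8 mitochondrially encoded mRNAs and 7 nuclear-retained RNAs were called lower in H69M. Glycolysis mRNAs were enriched in both lines (median 1.28, adjusted p = 1.37e-10 in H69, and 0.88, adjusted p = 5.90e-09 in H69M), a call lost at adjusted p = 0.415 and 0.431 with an estimated correlation. Ribosomal protein mRNAs had a median of 0.55 in H69 (20 of 79 higher, 2 lower) and -0.27 in H69M (0 higher, 4 lower). Without H69M shNTC polysomal replicate 1 or 2 the H69M median of mitochondrially encoded mRNAs was -1.20 and -3.16. Leaving out H69 shNTC cytoplasmic replicate 1, 2, polysomal replicate 1 or 2 gave 2, 3, 0 and 8 mitochondrially encoded mRNAs called in H69, and 4, 3, 2 and 7 nuclear-retained RNAs. The same 4 omissions in H69M shNTC gave 1, 0, 0 and 5 mitochondrially encoded mRNAs and 1, 2, 2 and 1 nuclear-retained RNAs. Over the same H69 omissions ribosomal protein mRNAs had medians of 0.59, 0.52, 0.77 and 0.30 in H69, the last without H69 shNTC polysomal replicate 2. Fewer than 20 were called higher each time. None of the 4 called lower in H69M stayed called, and the median there was -0.44 and -0.049 without H69M shNTC cytoplasmic replicate 1 or 2, and -0.14 without polysomal replicate 1.

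In H69 1531 genes were higher and 1201 lower on polysomes, in H69M 498 and 587; with the block within each line the counts were 2279 and 2081, and 1405 and 1159. Scaling by total library size alone moved the median of all genes by -0.345 in H69 and -0.248 in H69M (and by -0.136 in the cytoplasmic line difference), so these values are relative to TMM scaling. The H69 total of 2732 was 433 and 620 without H69 shNTC cytoplasmic replicate 1 or 2, and 794 and 1530 without polysomal replicate 1 or 2. The H69M total of 1085 was 289 and 110 without H69M shNTC cytoplasmic replicate 1 or 2, and 484 and 181 without polysomal replicate 1 or 2. It was 501 and 503 without H69 sheIF6 cytoplasmic replicate 1 or 2, and 637 and 643 without H69 shNTC cytoplasmic replicate 1 or 2.

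Knockdown against control in H69 is the labels' own comparison for the role of eIF6 in the parental line. HMCN1, a gene of a large extracellular matrix protein on chromosome 1, fell in polysomal RNA from 2.09 ± 0.127 to 0.0618 ± 0.0160 CPM (log2 -5.02, n = 2 per group); it was the 1 gene called there and was chosen after its values were seen. The call was lost without H69 sheIF6 polysomal replicate 1 or 2 (-4.79 and -5.30, adjusted p = 0.0764 and 0.160). WLS, which carries Wnt ligands to the cell surface, was at 5.996 ± 1.36 against 39.5 ± 22.2 CPM in cytoplasmic RNA (-2.72, SE 0.515, adjusted p = 0.380) and passed with the replicate block within each line (-2.59, adjusted p = 0.00257; polysomal -2.68, adjusted p = 0.00164). In polysomal RNA the block also called the Ras activator gene RASGRP1 (-2.76, adjusted p = 0.0144; 6.94 ± 0.578 against 51.2 ± 29.6), AIM1 (-3.06), LAMA4 (-1.84) and TBX2 (-1.92) lower. It called the potassium channel gene KCNS3 (3.54, adjusted p = 0.0210; 4.90 ± 0.859 against 0.418 ± 0.108) and the desmosome gene PKP2 (2.12, adjusted p = 0.0409) higher.

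Targets of ERK signalling were the group that moved furthest in H69. All 18 were lower in cytoplasmic RNA (median log2 -1.59, camera adjusted p = 7.04e-14) and 16 of 18 in polysomal RNA (median -1.43, or -1.31 with genes at 0 in a group at their bound; adjusted p = 4.41e-10). Both calls were lost, at adjusted p = 0.693 and adjusted p = 0.689 with an estimated correlation. Without H69 shNTC cytoplasmic replicate 1 the cytoplasmic median was -0.65 and the call was lost, and without H69 shNTC polysomal replicate 1 the polysomal median was -0.58. Adjusted over the list alone 2 members passed in each fraction: the phosphatase gene DUSP5 (-2.02, 0.502 ± 0.0110 against 2.05 ± 0.776 CPM; polysomal -1.57) and the cyclin gene CCND1 (-1.595, 1.12 ± 0.283 against 3.38 ± 2.07; polysomal -1.46). The cytoplasmic CCND1 value was -0.78 without H69 shNTC cytoplasmic replicate 1. Neuroendocrine genes of the panel did not pass: INSM1 was at 1971 ± 539 against 1894 ± 456 CPM on polysomes and CHGA moved by -0.42 and -0.39. CDH2 (-1.28 and -1.61) and MYC (-1.45 and -1.50) did not pass either.

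In cytoplasmic RNA of H69 genes of the non-neuroendocrine state (median -1.55, adjusted p = 2.13e-06), YAP and TEAD targets (-0.78, or -0.33 with genes at 0 at their bound; adjusted p = 0.000158), mesenchymal genes (-0.34), TGF-beta targets (-0.34) and matrix genes (-0.61) were lower. Epithelial genes (0.21) and large-subunit ribosomal proteins (0.17) were higher (adjusted p = 0.0102 and 0.0109). All 7 calls were lost, at adjusted p = 0.693 (matrix adjusted p = 0.876, ribosomal proteins adjusted p = 0.988) with an estimated correlation. Without H69 shNTC cytoplasmic replicate 1 the medians were 0.0547, 0.372, 0.134, 0.0146, 0.0146, 0.0900 and 0.188, and these calls and that of the ERK targets (-0.65) were lost. Without H69 sheIF6 cytoplasmic replicate 2 the epithelial (0.024), TGF-beta (-0.36), ribosomal protein (0.10) and matrix (-0.63) calls were lost, without sheIF6 replicate 1 the matrix call (-0.37) and without shNTC replicate 2 the ribosomal protein call (0.14). Calls that held moved as well: without shNTC replicate 2 the mesenchymal (-0.72), epithelial (0.63) and YAP (-1.49) medians, and without sheIF6 replicate 1 the mesenchymal (-0.57) and epithelial (0.41) medians. In H69 shNTC cytoplasmic replicate 1, 74 genes chosen as high in H69M and near 0 in the knockdown libraries of H69 had a median of 0.281% of their H69M level, against 0 to 0.0361% in the other 3 control libraries of H69.

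On polysomes of H69 epithelial genes were higher (0.29, adjusted p = 0.0170; adjusted p = 0.922 with an estimated correlation), a call lost without H69 shNTC polysomal replicate 1 (0.27), with a median of 0.45 without replicate 2. Fibroblast matrix genes were higher too (0.60, 9 genes, adjusted p = 0.0170; adjusted p = 0.585 with an estimated correlation), a call lost without H69 sheIF6 polysomal replicate 1 (0.57) or shNTC polysomal replicate 2 (0.072), with a median of 2.30 without shNTC polysomal replicate 1. Polysome association rose by list for fibroblast matrix genes (0.86, adjusted p = 8.81e-05), mesenchymal (0.18), non-neuroendocrine (0.91), matrix (0.33) and TGF-beta genes (0.16). Those calls were lost at adjusted p = 0.0858, 0.773, 0.987, 0.954 and 0.954 with an estimated correlation, and also without H69 shNTC cytoplasmic replicate 1 (0.94, -0.27, -0.57, -0.11 and -0.16). Without H69 shNTC polysomal replicate 2 all 5 were lost too (0.54, 0.011, 1.47, 0.33 and -0.014). Without H69 sheIF6 polysomal replicate 1 the mesenchymal (-0.049), matrix (0.29) and TGF-beta (0.093) calls were lost, and the TGF-beta call without H69 sheIF6 cytoplasmic replicate 1 (0.24) or 2 (0.43). Medians of calls that held were larger without H69 shNTC polysomal replicate 1, in the order above (1.50, 1.02, 1.72, 0.55 and 0.31). They were larger also without H69 shNTC cytoplasmic replicate 2 (fibroblast 1.32, mesenchymal 0.53, non-neuroendocrine 1.38, TGF-beta 0.41), sheIF6 polysomal replicate 2 (mesenchymal 0.45, TGF-beta 0.28), sheIF6 cytoplasmic replicate 1 (mesenchymal 0.37) or replicate 2 (matrix 0.52).

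By edgeR 0 genes were called in cytoplasmic RNA of H69 (696 at an unadjusted p under 0.05; 78 by DESeq2, 0 by limma-voom), 1 in polysomal RNA (956; 92 and 0) and 0 for polysome association (383; 3 and 0). With the block within each line the counts were 1, 25 and 0. Single omissions moved the cytoplasmic count to 38 (H69 shNTC cytoplasmic replicate 2), 4 (replicate 1) and 1 (H69M sheIF6 cytoplasmic replicate 1 or 2). They moved the polysomal count to 4 (H69 shNTC polysomal replicate 1 or 2), 3 (H69M sheIF6 polysomal replicate 1 or 2) and 2 (H69 sheIF6 polysomal replicate 1, H69 shNTC cytoplasmic or H69M shNTC polysomal replicate 1 or 2). The association count became 2 without H69M sheIF6 polysomal replicate 1 or 2, and 1 without H69 sheIF6 polysomal replicate 2, H69 shNTC cytoplasmic replicate 2 or H69M shNTC polysomal replicate 1.

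Knockdown against control in H69M is the same comparison in the second line. The Wnt antagonist gene FRZB rose 14.97-fold in cytoplasmic RNA, from 5.95 ± 4.15 to 89.1 ± 14.8 CPM (log2 3.90, SE 0.544, adjusted p = 0.0174, n = 2 per group), and the neuronal endosome gene NSG1 12.4-fold, from 0.396 ± 0.0757 to 4.95 ± 0.376 (3.63, SE 0.417, adjusted p = 0.0132). STMN2, a regulator of neuronal microtubules, rose from 4.58 ± 0.682 to 42.7 ± 13.4 CPM (3.22, adjusted p = 0.0147). The kinase gene ALPK2 fell 12.8-fold, from 84.2 ± 36.5 to 6.58 ± 2.31 (-3.68, SE 0.434, adjusted p = 0.0210), and CD82, a tetraspanin that restrains cell migration, 5.22-fold, from 40.1 ± 1.02 to 7.68 ± 0.798 (-2.38, SE 0.311, adjusted p = 0.0147). Without H69M sheIF6 or shNTC cytoplasmic replicate 1 none of the 36 genes called in cytoplasmic RNA passed, and the STMN2 call was lost also without H69M shNTC cytoplasmic replicate 2 (3.39, adjusted p = 0.0507).

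Other risers in cytoplasmic RNA were TNMD (at least 81.3-fold, 3.13 ± 0.953 CPM against 0), the Wnt inhibitor gene NKD2 (log2 4.48), the synaptic gene RIMS4 (3.66) and COL26A1 (3.27). Other genes that fell were PIK3CD (-3.05), IFFO2 (-2.55), the planar polarity gene CELSR1 (-2.43) and DFNA5 (-2.15), whose product forms pores in pyroptosis. On polysomes RIMS4 (3.48), COL26A1 (3.28), STMN2 (2.50, from 7.33 ± 3.84 to 41.5 ± 0.640), PPM1L (1.95), the growth factor gene GDF11 (1.47) and the adhesion gene CADM4 (1.42, from 39.7 ± 4.15 to 106 ± 13.1) rose. ALPK2 (-3.63), the potassium channel gene KCNMA1 (-3.33), DFNA5 (-2.27), CD82 (-2.20), MICALL1 (-1.37) and CDCP1 (-1.55, from 178 ± 5.35 to 60.8 ± 0.629), a membrane substrate of Src kinases, fell. No cytoplasmic call held without H69M sheIF6 or shNTC cytoplasmic replicate 1, and none of the 15 polysomal calls without H69M sheIF6 polysomal replicate 2.

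**Figure D2:**
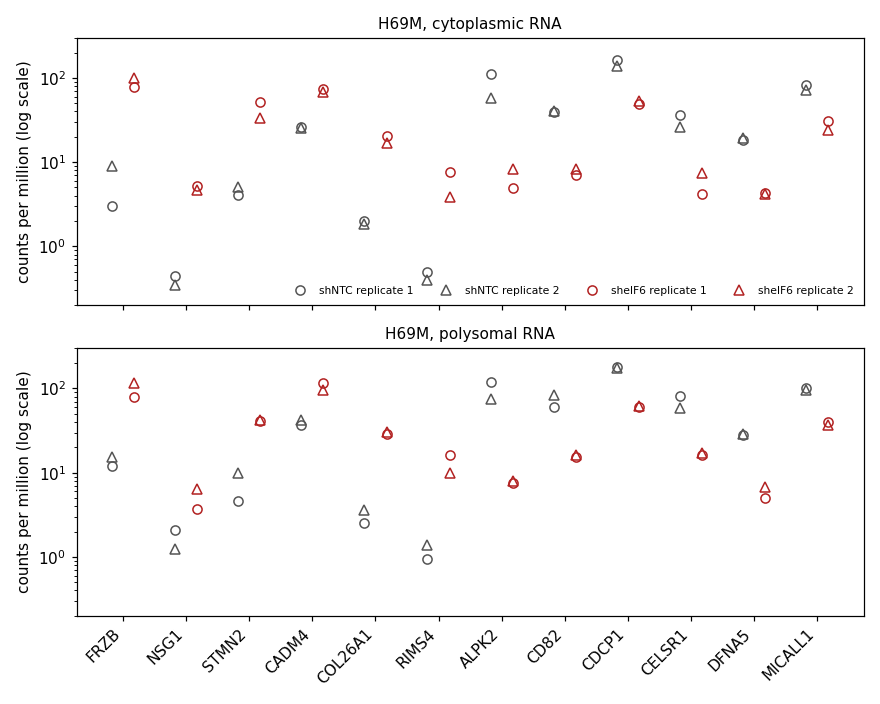
Levels of 12 genes in H69M cytoplasmic and polysomal libraries (log axis; grey shNTC, red sheIF6; circles replicate 1, triangles replicate 2).

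With the replicate block within each line further genes passed in H69M; those given here are members of the fixed lists and panel, picked after their values were seen. Of 25 matrix genes 3 passed in each fraction, all lower, while the medians of that list overlapped between knockdown and control libraries. COL12A1 was at 7.61 ± 3.87 against 88.3 ± 60.4 CPM in cytoplasmic RNA (blocked log2 -3.45, adjusted p = 0.00418), TNC at 33.8 ± 1.32 against 136 ± 79.8 (-1.88, adjusted p = 0.0152) and COL7A1 at 14.4 ± 0.298 against 44.2 ± 19.6 (-1.54, adjusted p = 0.0401). Unblocked, TNC moved from -2.01 to -1.24 and COL7A1 from -1.62 to -1.07 without H69M shNTC cytoplasmic replicate 1, and COL12A1 passed without H69M shNTC polysomal replicate 2 (-3.53, adjusted p = 0.0444). The hyaluronan receptor gene CD44 was lower on polysomes (-1.24, adjusted p = 0.0255; 225 ± 14.7 against 541 ± 186). So were the cadherin genes CDH3 (-1.56, adjusted p = 0.0314) and CDH1 (-1.66, adjusted p = 0.0407; cytoplasmic -1.76, adjusted p = 0.0271) and the tight junction gene OCLN (-1.58, adjusted p = 0.0386). The desmosome gene DSP was higher (1.58, adjusted p = 0.0101; 95.0 ± 7.84 against 33.1 ± 12.1). Of the panel YAP1 (-0.97, 132 ± 50.7 against 259 ± 20.2 CPM), VIM (0.45), REST (-0.74), AXL (-0.99), MYC (-0.80), CDH2 (-0.91), INSM1 (0.05), CHGA (0.11) and CDKN1A (-0.29) did not pass in cytoplasmic RNA.

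NF-kB and inflammatory genes were lower in H69M in both fractions: 20 of 22 in cytoplasmic RNA (median log2 -1.14, adjusted p = 4.04e-06; adjusted p = 0.272 with an estimated correlation) and 22 of 22 on polysomes (-1.30, or -1.20 at bounds; adjusted p = 2.95e-09; adjusted p = 0.178 with an estimated correlation). Without H69M shNTC replicate 1 of the fraction the medians were -0.75 and -0.54. None of the 22 passed over all genes. Adjusted over the list alone TNFAIP3 (-1.74, 17.0 ± 1.02 against 56.6 ± 26.5 CPM), NFKB1 (-0.997) and NFKB2 (-0.96) passed in cytoplasmic RNA, and with IL6 (-2.46) and IL32 (-1.42) on polysomes. TNFAIP3 was at -1.15 without H69M shNTC cytoplasmic replicate 1, and without polysomal replicate 1 the polysomal values were -0.88 (TNFAIP3, from -1.37), -0.59 (NFKB1, from -0.91) and -1.52 (IL6). Integrin and focal adhesion genes were lower (-0.47, adjusted p = 5.20e-05, and -0.36, adjusted p = 0.00115; adjusted p = 0.272 and 0.441 with an estimated correlation). Members that passed over the list alone in cytoplasmic RNA include ITGA6 (-1.09) and FERMT2 (-1.26, 254 ± 26.6 against 607 ± 54.6). The polysomal call was lost without H69M shNTC polysomal replicate 2 (-0.18). YAP and TEAD targets were lower in cytoplasmic RNA (-0.68, 21 of 22, adjusted p = 0.000961; adjusted p = 0.782 with an estimated correlation). Epithelial genes were lower on polysomes (-1.11, or -1.01 at bounds, adjusted p = 8.12e-05; adjusted p = 0.441 with an estimated correlation; -0.47 without H69M shNTC polysomal replicate 2 and -0.68 without sheIF6 polysomal replicate 1). There KRT7, CDH1, OCLN, CDH3, ST14, CLDN7 and EPCAM were lower and DSP higher over the list alone.

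Ribosomal protein mRNAs were higher in cytoplasmic RNA of H69M: 46 of 47 of the large subunit (median 0.75, adjusted p = 2.44e-19) and 32 of 32 of the small one (0.84, adjusted p = 5.68e-16), both lost at adjusted p = 0.782 with an estimated correlation. None passed over all genes. Over the list alone 29 and 13 did, such as RPL13A (1.15, 1399 ± 690.4 against 629.95 ± 59.9 CPM) and RPS15 (1.62, 1065 ± 760.3 against 347 ± 98.7). Without H69M sheIF6 cytoplasmic replicate 1 these 2 were at 0.54 and 0.61, and without replicate 2 both passed over all genes (1.59 and 2.22). Nuclear genes of oxidative phosphorylation were higher too (72 of 76, median 0.55, adjusted p = 1.53e-13; adjusted p = 0.796 with an estimated correlation). These 3 lists, and the NF-kB, integrin and YAP lists in cytoplasmic RNA, kept their call without any 1 H69M library. They were not tested again without libraries of H69. Their size depended on single libraries, however: without H69M sheIF6 cytoplasmic replicate 1 the medians of the 2 ribosomal protein lists and of oxidative phosphorylation were 0.38, 0.39 and 0.24, and without replicate 2 that of oxidative phosphorylation was 0.83. Part of the rise goes with the shortness of these mRNAs. Across 10349 protein-coding genes, length and the cytoplasmic change in H69M had a rank correlation of -0.406 (-0.168 without H69M sheIF6 cytoplasmic replicate 1), with a median change of 0.526 under 800 nt and -0.292 over 6000 nt. Ribosomal protein mRNAs together rose by a median of 0.764, against 0.395 for genes matched in annotated length, which can exceed that of the mRNA expressed. Oxidative phosphorylation genes, and the NF-kB, integrin and YAP lists, were not compared with genes matched in length.

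On polysomes of H69M the ribosomal protein and oxidative phosphorylation lists were not called (large subunit 0.155, adjusted p = 0.296; small subunit 0.188, adjusted p = 0.269; oxidative phosphorylation 0.0405, adjusted p = 0.427). The polysomal libraries of the knockdown lay on both sides of the controls. Relative to the mean of the 4 libraries, the large-subunit list was at -0.26 and 0.35 (sheIF6 replicates 1 and 2) and -0.15 and 0.060 (shNTC). The small-subunit list was at -0.29 and 0.37 against -0.24 and 0.092, and oxidative phosphorylation at -0.23 and 0.30 against -0.18 and 0.094. Lower association goes with the cytoplasmic rise, and the low polysomal level of sheIF6 replicate 1 also enters it. The change in association was -0.63 for the large subunit (0 of 47 positive, adjusted p = 2.21e-20) and -0.72 for the small one (0 of 32, adjusted p = 4.83e-16). It was negative also for oxidative phosphorylation (-0.48, 1 of 76, adjusted p = 1.93e-14) and the mitochondrial ribosome (-0.47, 2 of 73, adjusted p = 1.94e-13). These 4 calls were lost at adjusted p = 0.944 with an estimated correlation. Without H69M sheIF6 replicate 1 the 4 medians were -0.24, -0.22, -0.21 and -0.21 (cytoplasmic library left out) or -0.39, -0.40, -0.27 and -0.27 (polysomal). Without sheIF6 polysomal replicate 2 the first 3 were -1.01, -1.10 and -0.80. Without sheIF6 cytoplasmic replicate 2 the large-subunit median was -0.96 and that of oxidative phosphorylation -0.75, the latter -0.30 without shNTC cytoplasmic replicate 1.

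**Figure D3:**
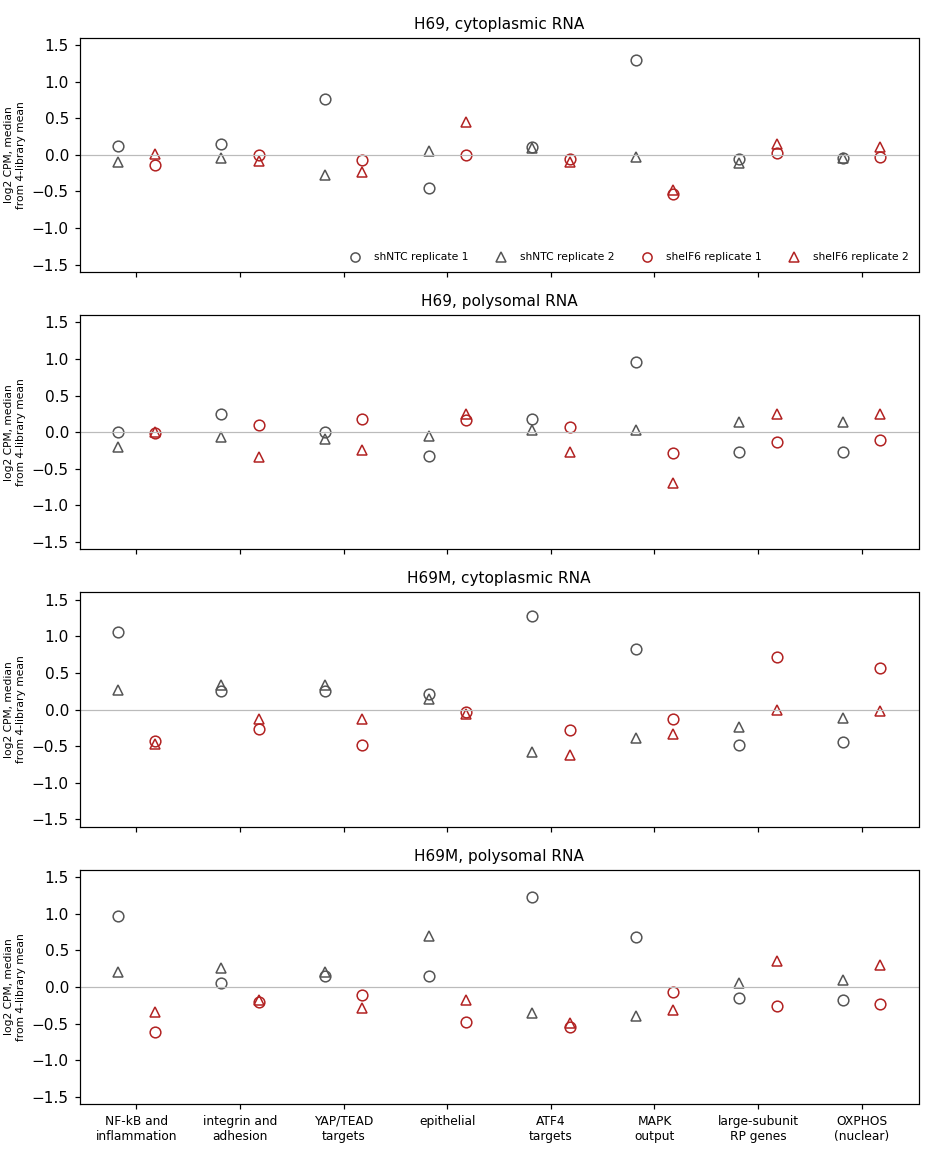
Median over the genes of 8 lists of log2 CPM in each library, relative to the mean of the 4 libraries of the same line and fraction.

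Targets of ATF4, the transcription factor of the integrated stress response, were lower in H69M: 29 of 31 in cytoplasmic RNA (median -1.11, adjusted p = 8.16e-08) and 29 of 31 on polysomes (-1.32, adjusted p = 2.05e-10), lost at adjusted p = 0.796 and 0.661 with an estimated correlation. The arginine transporter gene SLC7A1 passed over all genes in cytoplasmic RNA (-1.67, SE 0.287, adjusted p = 0.0479; 83.7 ± 29.4 against 266 ± 73.7 CPM), and STC2 (-3.02) and SLC7A5 (-1.32) over the list alone. The SLC7A1 call was lost without any 1 of 13 libraries, such as H69M sheIF6 or shNTC cytoplasmic replicate 1 (-1.34 and -1.35), and STC2 was at -1.82 without H69M shNTC cytoplasmic replicate 1. Without H69M shNTC cytoplasmic replicate 1 the cytoplasmic median was 0.21, and without polysomal replicate 1 the polysomal median was -0.011. Mitosis genes were higher in both fractions (0.35, adjusted p = 0.00119, and 0.49, adjusted p = 1.15e-06; lost at adjusted p = 0.796 and 0.661 with an estimated correlation). The cytoplasmic call was lost without H69M shNTC cytoplasmic replicate 1 (0.13) or sheIF6 cytoplasmic replicate 2 (0.21) and the polysomal one without H69M sheIF6 polysomal replicate 2 (0.060). The cytoplasmic median was 0.62 without H69M shNTC cytoplasmic replicate 2, and the polysomal one 0.79 without sheIF6 polysomal replicate 1 and 0.29 and 0.81 without shNTC polysomal replicate 1 or 2. Mitochondrially encoded mRNAs were higher on polysomes (0.80, 13 of 13, adjusted p = 7.46e-06; adjusted p = 0.661 with an estimated correlation; 0.13 and 2.03 without H69M shNTC polysomal replicate 1 or 2). Their share of counts was 1.37 ± 0.215% against 0.820 ± 0.693%, with controls at 0.330 and 1.31%.

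Other list changes in cytoplasmic RNA of H69M were higher medians for mitochondrial ribosome genes (0.28), other mRNAs with a terminal oligopyrimidine tract (0.46), sterol synthesis (0.36) and neuroendocrine genes (0.39, with STMN2 past the limit over all genes). Medians were lower for non-neuroendocrine (-0.67), ERK target (-0.78) and matrix genes (-0.54). All 7 were lost at adjusted p = 0.796 with an estimated correlation. Without H69M shNTC cytoplasmic replicate 1 the mitochondrial ribosome (0.21), sterol (-0.16), neuroendocrine (0.060), non-neuroendocrine (-0.15) and ERK target (0.36) calls were lost. Without H69M sheIF6 cytoplasmic replicate 1 those of the oligopyrimidine (0.30), mitochondrial ribosome (0.078), sterol (0.11) and matrix (-0.31) lists were. Without replicate 2 those of the neuroendocrine (-0.13), non-neuroendocrine (-0.60), ERK target (-0.68) and matrix (-0.38) lists were, and without H69M shNTC cytoplasmic replicate 2 that of the matrix list (-0.12). Calls that held moved without sheIF6 cytoplasmic replicate 2 (oligopyrimidine 0.72, mitochondrial ribosome 0.48, sterol 0.56), shNTC cytoplasmic replicate 2 (sterol 1.10, neuroendocrine 1.01, ERK targets -1.18) or sheIF6 cytoplasmic replicate 1 (neuroendocrine 0.78). On polysomes hypoxia genes were lower (-0.77, adjusted p = 0.000862; 0.27 without H69M shNTC polysomal replicate 1 and -0.65 without sheIF6 polysomal replicate 2). So were non-neuroendocrine genes (-0.55, adjusted p = 0.00302; -0.33 and -0.84 without H69M shNTC polysomal replicate 1 or 2). Both calls were lost, at adjusted p = 0.661 with an estimated correlation. YAP targets (-0.55, adjusted p = 0.0381) and FOXO targets (-0.52), matrix (-0.42), UPR (-0.17) and mitochondrial ribosome genes (-0.15; adjusted p = 0.0320 each) were lower on polysomes as well, and lost at adjusted p = 0.661 to 0.777 with an estimated correlation. Without H69M sheIF6 polysomal replicate 1 the matrix (-0.40), UPR (-0.068) and mitochondrial ribosome (0.021) calls were lost, and without replicate 2 the YAP (-0.44) and FOXO (-0.27) calls. Without H69M shNTC polysomal replicate 1 the YAP (-0.40) and FOXO (-0.55) calls were lost, and without replicate 2 all 5 (-0.30, -0.50, 0.15, -0.087 and -0.15). Calls that held moved without H69M shNTC polysomal replicate 1 (matrix -0.67, UPR -0.37) or sheIF6 polysomal replicate 2 (UPR -0.51, mitochondrial ribosome -0.28).

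Beyond ribosomal and mitochondrial mRNAs, polysome association in H69M fell by list for other oligopyrimidine mRNAs (-0.34), glycolysis (-0.36), epithelial (-0.34), translation initiation (-0.23) and neuroendocrine genes (-0.42), and rose for mitochondrially encoded mRNAs (0.52, 13 of 13 positive, adjusted p = 9.75e-05). With an estimated correlation these were lost, at adjusted p = 0.944 to 0.967. The oligopyrimidine call was lost without H69M sheIF6 cytoplasmic (-0.24) or polysomal (-0.090) replicate 1. The glycolysis call was lost without H69M sheIF6 cytoplasmic replicate 1 (-0.079), shNTC cytoplasmic replicate 2 (-0.33) or shNTC polysomal replicate 1 (-0.059). The epithelial call was lost without H69M sheIF6 cytoplasmic replicate 2 (-0.49), sheIF6 polysomal replicate 1 (-0.12) or shNTC polysomal replicate 2 (-0.17), and the initiation call without sheIF6 polysomal (-0.091), shNTC cytoplasmic (-0.34) or shNTC polysomal replicate 1 (-0.096). The neuroendocrine call was lost without H69M sheIF6 cytoplasmic replicate 2 (0.055), sheIF6 polysomal replicate 1 (0.052), shNTC cytoplasmic replicate 1 (-0.035) or shNTC polysomal replicate 2 (0.51). Relative to the mean of the 4 polysomal libraries that list was at 0.869 and 0.617 in replicate 2 (shNTC and sheIF6) and -0.817 and -0.558 in replicate 1. Genes of H69 alone stood at 9.39 and 6.0045% of their H69 level in replicate 2 and 0.323 and 0.540% in replicate 1. They were chosen to be low in replicate 1 and include SCG3, CHGA and SYT4 of the list, so the 2 contrasts are not independent. The mitochondrial call was lost without H69M sheIF6 cytoplasmic replicate 2 (0.33) or shNTC polysomal replicate 1 (-0.091). Calls that held moved without sheIF6 cytoplasmic replicate 1 (epithelial -0.53, neuroendocrine -0.81) or 2 (oligopyrimidine -0.53, glycolysis -0.69, initiation -0.46). Without sheIF6 polysomal replicate 2 the medians were -0.65 (oligopyrimidine), -0.84 (epithelial), -0.495 (initiation), -1.38 (neuroendocrine) and 0.33 (mitochondrially encoded). Without shNTC cytoplasmic replicate 1 the epithelial one was -0.56, and without replicate 2 the neuroendocrine one -0.89 and the mitochondrially encoded one 0.30. Without shNTC polysomal replicate 1 the neuroendocrine one was -1.15, and without replicate 2 initiation was at -0.39 and mitochondrially encoded mRNAs at 1.76.

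By edgeR 21 genes were higher and 15 lower in cytoplasmic RNA of H69M, 7 and 8 on polysomes, and 0 changed in polysome association (392 at an unadjusted p under 0.05; 1 by DESeq2, 0 by limma-voom). With the block within each line the counts were 129 and 139, 84 and 119, and 0, and they held all 36 and all 15 of the genes called without it. The cytoplasmic total of 36 became 0 without H69M sheIF6 or shNTC cytoplasmic replicate 1, 105 and 18 without replicate 2 of the same groups, 20 and 21 without H69 sheIF6 cytoplasmic replicate 1 or 2 and 23 without H69 sheIF6 polysomal replicate 1. The polysomal total of 15 became 0 without H69 or H69M sheIF6 cytoplasmic replicate 1 or 2, H69 sheIF6 polysomal replicate 1 or H69M sheIF6 polysomal replicate 2. It became 8 without H69 sheIF6 polysomal replicate 2, 2 without H69M sheIF6 polysomal replicate 1, and 1 and 4 without H69M shNTC polysomal replicate 1 or 2. The association count became 3 without H69M sheIF6 polysomal replicate 1 and 1 without H69M shNTC polysomal replicate 1.

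The difference of the knockdown between lines asks whether H69 and H69M responded unlike. FRZB rose in H69M but was at 4.68 ± 0.656 against 14.8 ± 5.99 CPM in H69 (difference of log2 changes 5.57, SE 0.734, edgeR adjusted p = 0.0374, n = 2 per group). GATA6, an endoderm transcription factor gene, was at 13.4 ± 1.72 against 37.2 ± 2.43 in H69M and 1.95 ± 0.522 against 0.0781 ± 0.110 in H69 (-6.06, SE 0.850). That value rests on 8 counts in H69 shNTC cytoplasmic replicate 1 and 0 in replicate 2; the fitted value was -10.98 without the former, which leaves a control at 0, and -5.09 without the latter. CDCP1 was at 50.9 ± 3.18 against 152 ± 18.8 in H69M and 37.0 ± 1.07 against 25.3 ± 5.23 in H69 (-2.13). On polysomes HMCN1 differed (5.75, SE 0.630, adjusted p = 0.0139), at 137 ± 2.75 against 82.4 ± 17.3 CPM in H69M. In cytoplasmic RNA 3 genes differed upwards and 4 downwards, with 7 called in both fits and 32 with the block within each line; on polysomes 1 did, against 37.

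The cytoplasmic total of 7 became 4 without H69 shNTC cytoplasmic replicate 1, 1 without H69M shNTC cytoplasmic replicate 2 and 0 without any 1 of 13 others. Of the 16 omissions only that of H69 shNTC cytoplasmic replicate 2 kept 7, while the FRZB difference stayed between 4.99 and 6.55. The HMCN1 call was lost without H69 sheIF6 polysomal replicate 1 or 2, H69 shNTC polysomal replicate 2 or H69M sheIF6 polysomal replicate 1 (adjusted p = 0.0832, 0.117, 0.0592 and 0.0755). Across 23100 genes, which are not independent replicates, the knockdown changes of the 2 lines had a rank correlation of 0.143 in cytoplasmic and 0.104 in polysomal RNA (0.294 and 0.215 for 11233 genes with a mean log2 CPM over 3). The cytoplasmic value was 0.057 and 0.093 without H69 sheIF6 or shNTC cytoplasmic replicate 2, 0.086 without H69M sheIF6 cytoplasmic replicate 1 and 0.089 without H69M shNTC cytoplasmic replicate 2. The polysomal value was -0.011 without H69 sheIF6 polysomal replicate 2, 0.022 without H69 shNTC polysomal replicate 1, 0.063 without H69M sheIF6 polysomal replicate 2 and 0.070 without H69M shNTC polysomal replicate 2.

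The cytoplasmic knockdown changes were also set against the polysomal difference between the control lines. No library is shared, but cytoplasmic and polysomal controls of H69M deviated together (r = 0.578). Such deviations enter the 2 sides with opposite sign in H69M and push towards a negative trend there. How much of the trend they make was not measured, so it cannot be read as an effect of the knockdown. The 4251 genes higher in H69M polysomes had a median change of -0.21 in H69M (camera p = 5.64e-06; p = 0.00352 with an estimated correlation) and the 3608 genes higher in H69 one of 0.21 (p = 2.00e-07; p = 0.0952). In H69 the 4251 genes had a median of -0.042 (camera p = 0.0197; p = 0.0723 with an estimated correlation) and the 3608 genes one of -0.015 (p = 0.906; p = 0.967). The rank correlation of the changes was -0.214 in H69M and -0.0418 in H69. It was -0.098 in H69M without H69M shNTC cytoplasmic replicate 1. In H69 it was -0.019 and -0.0015 without H69 shNTC cytoplasmic replicate 1 or 2, and -0.064 and -0.00087 without polysomal replicate 1 or 2. With the line difference from the sheIF6 polysomal libraries, shared deviations act in the other direction in each line. They push towards a positive trend in H69M and a negative one in H69. The medians were then -0.093 and 0.066 in H69M (p = 0.0933 and 0.0746; p = 0.184 and 0.486 with an estimated correlation). In H69 the 4383 genes higher in H69M had a median of -0.062 (camera p = 0.000588; p = 0.0195 with an estimated correlation) and the 3988 genes higher in H69 one of 0.0080 (p = 0.241; p = 0.645). The correlations were -0.0713 in H69M and -0.0905 in H69.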

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

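A test of the difference of the knockdown between lines picked out the genes and lists in the next 2 paragraphs, as fixed before the data were examined; all 9 tests of explanations after them, and the omissions of pairs of libraries with 1 number, were chosen after the results had been seen.

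In cytoplasmic RNA the knockdown change in H69M minus that in H69 was 5.57 for FRZB, 3.96 for NSG1 and 1.88 for CADM4, and -6.06 for GATA6, -3.93 for IFFO2, -3.42 for NHSL2 and -2.13 for CDCP1 (log2; adjusted p = 0.0374 for each). NSG1 was at 21.003 ± 2.70 against 26.4 ± 9.33 CPM in H69, CADM4 at 20.6 ± 1.19 against 27.2 ± 3.86, IFFO2 at 3.60 ± 0.358 against 1.37 ± 0.0930 and NHSL2 at 6.66 ± 1.00 against 1.47 ± 0.380. In polysomal RNA HMCN1 differed by 5.75 (adjusted p = 0.0139).

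Of the lists, the difference of the changes in cytoplasmic RNA had a median of 0.58 for large-subunit ribosomal proteins (adjusted p = 1.32e-09), 0.69 for small-subunit ones (2.62e-09), 0.45 for oxidative phosphorylation (2.70e-07), 0.22 for the mitochondrial ribosome (0.0202), 0.40 for other oligopyrimidine mRNAs (0.0202). It was 0.48 for mitosis (0.000489), 0.36 for sterol synthesis (0.0202), 0.41 for neuroendocrine genes (0.0126) and 1.26 for ERK targets (0.0332). It was -0.95 for ATF4 targets (2.87e-05), -0.73 for NF-kB genes (0.00154), -0.59 for epithelial genes (0.0119) and -0.29 for integrin genes (0.0202). In polysomal RNA it was -1.46 for epithelial genes (1.45e-07), -1.78 for NF-kB genes (1.08e-06), -1.02 for ATF4 targets (1.59e-05), -0.20 for the mitochondrial ribosome (0.00732), 0.56 for mitosis (1.81e-05) and 0.77 for ERK targets (0.0275). With an estimated correlation every one of these was lost (adjusted p = 0.928 in cytoplasmic RNA; in polysomal RNA adjusted p = 0.180 for epithelial and NF-kB genes and 0.956 for the others). With the replicate block within each line the cytoplasmic difference of ERK targets was lost too (adjusted p = 0.0619). Over the list alone STMN2 (3.33), CDH3 (-2.39) and TNFAIP3 (-2.09) differed in cytoplasmic RNA, and 10 epithelial genes in polysomal RNA, with DSP (1.34) up and KRT19 (-2.41), OCLN (-2.11), ELF3 (-2.07) and CDH3 (-1.90) down.

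Without any 1 library the NF-kB difference kept its call in both fractions and the epithelial one in polysomal RNA. The NF-kB one moved to -0.25 and -0.76 without H69M shNTC replicate 1 of the fraction, and to -1.29 without H69 shNTC cytoplasmic replicate 1. NF-kB genes stood a median of log2 3.87 higher in cytoplasmic controls of H69M. Medians at bounds were not taken for differences, so H69 genes near 0 can enter them. Others depended on single libraries. The cytoplasmic difference of ERK targets was -0.17 without H69 shNTC cytoplasmic replicate 1, and its call was also lost without H69 sheIF6 cytoplasmic replicate 2 (1.16), H69M sheIF6 cytoplasmic replicate 1 or 2 (0.95 and 1.35), or H69M shNTC cytoplasmic replicate 2 (0.60). The mitosis call was lost without H69M shNTC cytoplasmic replicate 1 (0.20) or sheIF6 cytoplasmic replicate 2 (0.36), and the neuroendocrine call without the same 2 libraries (0.37 and -0.011). The epithelial call was lost without H69 shNTC cytoplasmic replicate 1 (-0.52) or replicate 2 of H69 or H69M sheIF6 cytoplasmic RNA (-0.53 and -0.67). The integrin call was lost without H69 sheIF6 cytoplasmic replicate 1 (-0.19), H69 shNTC cytoplasmic replicate 2 (-0.23), H69M sheIF6 cytoplasmic replicate 1 (-0.14) or H69M shNTC cytoplasmic replicate 2 (-0.29). Without H69 shNTC, H69M sheIF6 or H69M shNTC cytoplasmic replicate 1 the calls of sterol synthesis (0.27, 0.18 and -0.073), other oligopyrimidine mRNAs (0.25, 0.21 and 0.33) and the mitochondrial ribosome (0.20, 0.062 and 0.13) were lost. The last was also lost without H69 sheIF6 cytoplasmic replicate 1 (0.22), and the oligopyrimidine call without replicate 2 (0.40). Those of the ribosomal proteins and oxidative phosphorylation were lost without H69M sheIF6 cytoplasmic replicate 1 (0.18, 0.22 and 0.16). That of ATF4 targets was 0.40 without H69M shNTC cytoplasmic replicate 1 and 0.20 in polysomal RNA without H69M shNTC polysomal replicate 1. In polysomal RNA the ERK target call was lost without H69 shNTC polysomal replicate 1 (-0.056), H69 sheIF6 polysomal replicate 2 (0.49) or H69M shNTC polysomal replicate 2 (0.38), and the mitosis call without H69 shNTC polysomal replicate 1 (0.26), H69M sheIF6 polysomal replicate 2 (0.084) or H69M shNTC polysomal replicate 1 (0.25). The mitochondrial ribosome call there was lost without H69 shNTC polysomal replicate 1 (-0.14), H69M sheIF6 polysomal replicate 1 (-0.049) or H69M shNTC polysomal replicate 2 (-0.16). Calls that held moved in cytoplasmic RNA without H69M sheIF6 cytoplasmic replicate 2: ribosomal proteins 0.94 and 1.08, oxidative phosphorylation 0.74, mitochondrial ribosome 0.43, oligopyrimidine 0.63, sterol synthesis 0.62 and ATF4 targets -0.56. So they did without H69M shNTC cytoplasmic replicate 2 (oxidative phosphorylation 0.70, mitochondrial ribosome 0.38, sterol synthesis 1.10, mitosis 0.73, neuroendocrine 0.98) or replicate 1 (oxidative phosphorylation 0.27, epithelial -0.39, integrin -0.11, ERK targets 2.07). The integrin median was -0.48 without H69 shNTC cytoplasmic replicate 1, and the neuroendocrine one 0.62 without H69 sheIF6 cytoplasmic replicate 2 and 0.75 without H69M sheIF6 cytoplasmic replicate 1. In polysomal RNA ERK targets were at 1.40 without H69M shNTC polysomal replicate 1 and the mitochondrial ribosome at -0.41 without H69M sheIF6 polysomal replicate 2.

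The first pattern is the fall of 5 lists of H69M-like genes in cytoplasmic RNA of H69, and the trace of each line's genes in libraries of the other. The fall rests on H69 shNTC cytoplasmic replicate 1, without which all 5 calls were lost. Of 50 genes of H69M alone outside the 5 lists, that library held a median of 0.206% of the H69M level. At that share 16 would have at least 10 counts there, taken from the lowest H69M library, and 9 of these lay within 4-fold of it. But 3 had under 10% of those counts: KRT17 (0 against 37.2), CNN1 (0 against 21.4) and IGFN1 (4 against 85.2). That count of 3 is the bound itself, and this is the third form of the test: the loss of the calls only repeated the pattern, and a share within 4-fold decided nothing. It argues only weakly against RNA or cells of H69M as the source of the fall, which stay possible. RNA from another source, the state of that sample and an effect of the knockdown were not tested and stay open. Genes of H69 alone stood at medians of 1.86, 2.04, 6.0045 and 9.39% of their H69 level in the H69M libraries numbered 2, against 0.157 to 0.540% in those numbered 1, in which they had been chosen to be low. At least 89.2% of the 37 genes lay within 4-fold of the median in each library, just under the 90 set for H69 RNA, and H19 lay more than 10-fold under it. RNA or cells of H69 and a few H69M cells that express neuroendocrine genes cannot be told apart for these libraries, since that value fell between the bounds. For the 21 genes that rose in H69M, RNA of H69 could cover at most 12.5% of the rise, which argues against it as their source.

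The second pattern is the fall of ATF4 and ERK targets in H69M. Without both H69M shNTC libraries numbered 1 the ATF4 median was 0.20 in cytoplasmic and -0.011 in polysomal RNA, and that of ERK targets 0.35 in cytoplasmic RNA. The omission of each alone had already given 0.21, -0.011 and 0.36, so these values repeat what raised the question and decide nothing. STC2 was at 527 ± 418 CPM in the cytoplasmic controls. The labels do not say whether these libraries share a culture. A state of the control samples numbered 1 and an effect of the knockdown cannot be told apart for these lists.

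The third pattern is the rise of ribosomal protein mRNAs in H69M cytoplasmic RNA and their lower polysome association. That rise and their low level in polysomal sheIF6 replicate 1 enter it. Their cytoplasmic median change was 0.764, and each lay a median of 0.465 above the 50 protein-coding genes nearest in length (quartiles 0.235 and 0.728). This argues against length as the whole cause of the rise only as far as the annotated lengths hold, and genes matched in length rose by 0.395. Length was that of the longest transcript with the best APPRIS rank in the annotation, not of the mRNA expressed here. It was 7686 nt for RPL37 and 7072 nt for RPL14, against a median of 1004 nt. A gene given too long a transcript is matched to long mRNAs, which changed the other way, and this enlarges its difference. The rank correlation of length with the cytoplasmic change was -0.406 in H69M, -0.168 without H69M sheIF6 cytoplasmic replicate 1 and -0.235 in H69. For association their median change was -0.66 and that of genes matched in length -0.37. The median difference from the 50 protein-coding genes nearest in length was -0.35 (quartiles -0.58 and -0.14). With the same limit on the lengths used, this argues against length as the whole cause. RPL13, given 4498 nt, was matched to genes at 0.117 and differed from them by -1.11. Without both H69M sheIF6 libraries numbered 1 the median was 0.045. The omissions of each alone, -0.22 and -0.39, already add up to 0.052, so this decides nothing either, and a state of the samples numbered 1 and an effect of the knockdown cannot be told apart. Across 10349 protein-coding genes, length and the change in association had a rank correlation of 0.584, which was -0.130 without that pair and 0.030 in H69.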

How the results depend on the processing

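With 2 libraries per group the spread, not depth, sets the limit. Where no cause is given for a change below, it was not tested.

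For 87 results of named genes the alternatives other than omission of a library gave 1150 values: 883 kept direction and side of the limit, 139 lost the call, 127 gained it and 1 reversed. Leaving out 1 library gave 1392 values, of which 1097 kept both, 289 lost the call, 5 gained it and 1 reversed. For 73 list calls 1742 values held 1357 kept calls, 333 lost calls of the same direction and 52 medians of the opposite sign. Leaving out each library in turn removes a residual degree of freedom, so lost calls are partly a matter of fewer samples.

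By DESeq2 the calls were 78, 92 and 3 in H69 (cytoplasmic, polysomal, association), 458, 336 and 1 in H69M, and 95 and 112 for the difference between lines (cytoplasmic, polysomal). They were 4297 and 2809 for polysomal against cytoplasmic RNA in H69 and H69M, and EIF6 in H69M polysomal RNA changed by -1.22. The 36 and 15 genes of edgeR were all among the H69M calls of DESeq2. By limma-voom the counts were 0 in H69 polysomal RNA, 102 and 42 in H69M, 0 and 0 for the difference, and the correlation of the H69M change with the line difference was -0.157.

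With the replicate block within line the counts were 1 and 25 in H69, 268 and 203 in H69M, and 32 and 37 for the difference. They were 4360 and 2564 for polysomal against cytoplasmic RNA, and the correlations with the line difference were -0.0181 (H69) and -0.178 (H69M). With a common replicate block for both lines they were 2 in H69 polysomal RNA, 72 and 29 in H69M and 0 for the cytoplasmic difference. The block within line also called lists: UPR genes in H69 polysomal RNA (median -0.19, adjusted p = 0.0419), ERK targets (-0.52, 0.0220) and glycolysis (-0.21, 0.0352) in H69M polysomal RNA, and UPR (-0.29, 0.0115), hypoxia (-0.38, 0.0115) and nuclear-retained RNA (0.37, 0.0114) in H69M association. It called the non-neuroendocrine (-0.42, 0.0352) and mitochondrially encoded (0.43, 0.0219) lists in the polysomal difference, sterol synthesis (-1.09, 0.0297), heat shock (-1.17, 0.00368) and mitosis (-0.89, 0.00159) in the cytoplasmic line difference, and fibroblast matrix genes (0.87, 0.0272) for polysomal against cytoplasmic RNA in H69M. The calls of ERK targets were lost in the cytoplasmic difference and in the polysomal line difference (1.57, adjusted p = 0.0636); the block changed no other list call. In a fit of 1 line alone with the replicate block the counts were 62, 114 and 7 in H69, 74 and 58 in H69M, and 7168 and 268 for polysomal against cytoplasmic RNA. EIF6 in H69 polysomal RNA was at -0.83 there, with 8 lists in H69 polysomal RNA, 0 in H69 association, and a cytoplasmic correlation between lines of 0.183. In a fit of 1 line alone without a block they were 4 and 3 in H69 (polysomal, association), 9 and 0 in H69M, and 4318 and 0 for polysomal against cytoplasmic RNA. There were 7 and 2 lists in H69 (polysomal, association) and a correlation of 0.183.

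Without a low-count filter, which tests more genes, the counts were 2 and 4 in H69, 55 in H69M cytoplasmic RNA and 12 for the cytoplasmic difference. Lists were 5 in H69 cytoplasmic RNA and 10 for the polysomal difference, with a cytoplasmic correlation between lines of 0.0754 and correlations with the line difference of -0.0206 (H69) and -0.132 (H69M). With the stricter filter the correlations between lines were 0.187 and 0.150. With total library size alone the counts were 0 in H69M polysomal RNA and 1 for the cytoplasmic difference. With genes over 5 times higher in the other line left out (2925 for H69, 2379 for H69M) they were 0 in H69 polysomal RNA, 2 lists in H69 cytoplasmic RNA and 0 in H69 association, with a correlation between lines of 0.177. There the YAP median in H69 cytoplasmic RNA was 0.24 and the matrix median in H69 association -0.028. With the line difference from sheIF6 libraries the correlations were -0.0905 (H69) and -0.0713 (H69M). With an estimated correlation, and by fry, 0 lists were called in each of the 6 knockdown contrasts and 2 differences.

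Without both H69 shNTC libraries numbered 1 the counts were 4 and 4 in H69, 1 and 2 for the difference, 4611 and 5085 between lines, and 1 for polysomal against cytoplasmic RNA in H69. Lists were 0, 3 and 14 (H69 cytoplasmic, H69 association, polysomal difference), with a correlation with the line difference of -0.00359. Medians there were 0.055 (non-neuroendocrine), 0.13 (mesenchymal), 0.37 (YAP), 0.015 (TGF-beta) and 0.015 (matrix) in H69 cytoplasmic RNA, -0.22 (non-neuroendocrine) and -0.099 (TGF-beta) in H69 association, and -0.17 and -0.056 for ERK targets in the cytoplasmic and polysomal difference. Without both H69M shNTC libraries numbered 1 the counts were 18 and 6 in H69M, 0 for the cytoplasmic difference and 93 for polysomal against cytoplasmic RNA. There were 8 and 6 lists in H69M (cytoplasmic, association), 8 and 11 for the difference and a correlation of -0.155. The NPTX1 difference was 0.037 there, and medians were 0.35 (ERK targets), -0.17 (sterol synthesis) and 0.20 (ATF4 targets) in H69M cytoplasmic RNA, 0.27 (hypoxia) in polysomal RNA, -0.083 (sterol synthesis) and 0.39 (ATF4 targets) in the cytoplasmic and 0.20 (ATF4 targets) in the polysomal difference. Without both H69M sheIF6 libraries numbered 1 the counts were 2, 1 and 2 in H69M and 1 for the cytoplasmic difference, with 2 lists in H69M association and 7 and 15 for the difference. Medians were 0.021 (mitochondrial ribosome, polysomal) and, in association, 0.078 (small-subunit ribosomal proteins), 0.039 (other oligopyrimidine mRNAs), 0.013 (translation initiation) and 0.062 (oxidative phosphorylation). Without the H69M polysomal libraries numbered 2 the counts were 0 in H69M polysomal RNA and 144 for polysomal against cytoplasmic RNA, with 16 lists in H69M association, 15 for the polysomal difference and a matrix median of 0.078 in polysomal RNA.

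Over the 16 omissions of 1 library the counts ran from 0 to 38, 1 to 4 and 0 to 2 in H69, and 0 to 105, 0 to 21 and 0 to 3 in H69M. They ran from 0 to 7 and 0 to 4 for the difference, 4530 to 7164 and 5270 to 7707 between lines, and 433 to 2740 and 110 to 1097 for polysomal against cytoplasmic RNA. Lists ran from 0 to 12, 2 to 14 and 1 to 9 in H69, 9 to 16, 9 to 19 and 9 to 18 in H69M, and 6 to 17 and 6 to 17 for the difference. Lists of a knockdown contrast within 1 line were tested only without a library of that line, which holds for the list medians below too. EIF6 ran from -0.81 to -0.75 and -0.90 to -0.78 in H69 and from -0.93 to -0.18 and -1.61 to -0.85 in H69M. Correlations ran from 0.0574 to 0.156 and -0.0114 to 0.117 between lines, and from -0.0642 to -0.000872 (H69) and -0.246 to -0.0980 (H69M) with the line difference. NPTX1 ran from -6.68 to 0.048.

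Medians that changed sign over these omissions ran, in H69 cytoplasmic RNA, from -2.11 to 0.055 (non-neuroendocrine), -0.72 to 0.13 (mesenchymal), -1.49 to 0.37 (YAP), -0.52 to 0.015 (TGF-beta) and -0.63 to 0.015 (matrix). In H69 association they ran from -0.57 to 1.72 (non-neuroendocrine), -0.27 to 1.02 (mesenchymal), -0.16 to 0.43 (TGF-beta) and -0.11 to 0.55 (matrix). In H69M cytoplasmic RNA they ran from -0.13 to 1.01 (neuroendocrine), -1.18 to 0.36 (ERK targets), -0.16 to 1.10 (sterol synthesis) and -1.54 to 0.21 (ATF4 targets). In H69M polysomal RNA they ran from -0.28 to 0.021 (mitochondrial ribosome), -0.99 to 0.27 (hypoxia) and -0.67 to 0.15 (matrix), and in H69M association from -1.38 to 0.51 (neuroendocrine) and -0.091 to 1.76 (mitochondrially encoded). In the cytoplasmic difference they ran from -0.011 to 0.98 (neuroendocrine), -0.17 to 2.07 (ERK targets), -0.073 to 1.10 (sterol synthesis) and -1.40 to 0.40 (ATF4 targets), and in the polysomal one from -0.056 to 1.40 (ERK targets) and -1.51 to 0.20 (ATF4 targets).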

Other observations

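No explanation was tested for the values in this part; the lists were fixed beforehand, while the single genes were chosen after their values were seen. Genes for late maturation and export of the large ribosomal subunit, the step at which eIF6 acts, were not called as a list in either line. Their 18 members had a median log2 change of -0.0153 (adjusted p = 0.964) and -0.0259 (0.909) in H69, and -0.149 (0.497) and -0.217 (0.0564) in H69M, cytoplasmic and polysomal. Genes of rRNA processing, 29 in number, had medians of 0.00446, -0.0404, 0.0098 and -0.149 (adjusted p = 0.977, 0.838, 0.915 and 0.181). Between the control lines these genes did differ. Those of rRNA processing were lower in H69M cytoplasmic RNA (median -0.50, adjusted p = 0.00876; adjusted p = 0.718 with an estimated correlation), among them BOP1 (-2.10), DKC1 (-1.25) and NOLC1 (-1.07). The NOLC1 call was lost without H69 shNTC cytoplasmic replicate 1 or 2 (-0.999 and -1.13) or H69M shNTC cytoplasmic replicate 1 or 2 (-0.99 and -1.15). EFL1, the GTPase that works with SBDS to release eIF6, was higher (1.27, adjusted p = 0.00245). EIF6 itself was at log2 0.69 (adjusted p = 0.0952).

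Genes linked to drug response differed between the control lines. SLFN11, whose product sensitises cells to DNA-damaging drugs, was higher in H69M (log2 8.24), as were the efflux transporter genes ABCC3 (5.76) and ABCG2 (4.71). Without H69 shNTC cytoplasmic replicate 1 the fitted values of SLFN11 and ABCG2 were 14.6 and 8.98, and the ABCG2 call was lost without replicate 2 (3.75, adjusted p = 0.0627). The list of 14 genes had 7 higher and 1 lower (adjusted p = 0.0210; adjusted p = 0.136 with an estimated correlation). In H69M cytoplasmic RNA under knockdown ADAMTS12, a matrix protease gene, was lower (blocked log2 -7.13, adjusted p = 0.0140; 5 counts in its 2 knockdown libraries together; unblocked -7.00, adjusted p = 0.126, with -5.92 and -10.8 without H69M sheIF6 cytoplasmic replicate 1 or 2), and the BMP antagonist gene SOSTDC1 higher (3.98, adjusted p = 0.0107; 14.98 ± 2.45 against 0.968 ± 0.309 CPM), with the replicate block within line. ADAMTS12 had no count in the H69M knockdown polysomal libraries against 8.20 ± 4.43 CPM in controls (at least 240-fold lower).

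The knockdown libraries of H69M cytoplasmic RNA were the deepest, at 87269772 and 60662256 counts, against 36005326 and 37527469 in their controls.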
